A study of Rattus norvegicus with 18 samples.

How the data were processed

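The material was tissue of the suprachiasmatic nucleus (SCN), the hypothalamic cell group that holds the main circadian clock of mammals, dissected from adult male Long-Evans rats. Per the labels, the animals had lived in alternating light and dark, were moved to constant darkness at the usual time of lights-off, and were sampled from the next projected lights-on (circadian time, CT, 0) every 6 h. RNA was extracted from each of the 5 rats of a time point and then pooled. Here 1 RNA pool was assumed for each of the 8 time points analysed (0, 6, 12, 18, 24, 30, 36 and 42 h). RNA was hybridised to the rat U34A GeneChip, a 1-colour oligonucleotide array on which a gene is read by 1 or more sets of short probes. Of the 18 arrays, 10 belonged to a first run, which held a pair of arrays marked a and b at 24 h and at 36 h, and 8 to a technical repeat with 1 array per time point. The immortalised SCN cell line named in the study's title was not analysed here.

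The values are the authors' deposited probe set intensities on a linear scale. The algorithm that summarised the probes, its version and the scaling target are not given in the sources used here. The deposited values were already scaled per array, since the mean after trimming 2% of the values at each end lay between 500.7 and 500.8 on the 18 arrays, and they were kept as deposited. The number of arrays limits the precision.

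From these intensities, values below the 10th percentile of the whole table (12.1) were set to that floor and all values were transformed to log2. Arrays a and b of a time point were averaged first, then the first run and the technical repeat. Both runs thus weighed equally in each pool. The 59 control probe sets of the 8799 were left out of every test. A probe set was tested when its mean over the 8 pools lay above the median of all probe sets, a geometric mean intensity of 121, which left 4370 probe sets and 2820 genes. Gene symbols came from the platform annotation of the array. There, 7006 probe sets had 1 gene symbol, 308 had several and 1426 had none, and only those with 1 symbol were named. The table of current RefSeq genes held the gene number of 6994 of the 7006 and changed 0 symbols; it was used for names only, and also updated older symbols in the gene lists.

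The replicate was the pool. The labels call the arrays of the technical repeat technical replicates. They do not state that arrays a and b read the same pool, which was assumed here. A cosine and sine of a 24 h period were fitted to the 8 pool means with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 5 residual degrees of freedom, 5.13 prior degrees of freedom). The test of a rhythm was limma's moderated F test of both terms, with Benjamini-Hochberg adjustment over the tested probe sets and a threshold of 0.05. The amplitude is the distance from the fitted mean to the fitted peak on the log2 scale, and the peak is given in CT. The difference between CT 6 and CT 18 and that between CT 12 and CT 0 were read from the sine and the cosine of the same fit, with 2 pools per phase. The second day (24 to 42 h) was set against the first (0 to 18 h) with a day term added to the cosine and sine, 4 pools per day. For single genes an exact permutation test of the 8 pools over the time points was added, in which 315 distinct arrangements set the smallest reachable p to 0.00317. Agreement of the cycles was measured across probe sets, which are not independent replicates, and compared with 100 other arrangements of the pools.

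Gene lists were tested with limma's camera, with a preset correlation between genes of 0.01, on 1 probe set per gene (that with the highest mean). There were 21 lists and 3 contrasts, hence 63 list tests adjusted together. The clock list named Bmal1 by an older symbol and lacked it as first matched. Bmal1 is in the list with updated symbols, which is used here. The tests, the replicate unit, the gene lists, the alternatives listed below and the rule for naming genes were fixed before the data were examined. That rule takes every measured gene of the clock list, the rhythmic genes past the threshold, filled up to 12 by the smallest p of the rhythm test where fewer passed, 5 genes in each direction of the day comparison by p where fewer passed, and up to 4 members of each list by p. The alternatives were quantile normalization, scaling to the median, no level filter or one at the 75th percentile, a pseudocount or a floor at the 25th percentile, limma with trend and robust, either run alone, arrays a or b left out, each pool left out in turn, other designs and other list tests.

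The fits were tested on simulated pools for 4370 probe sets, with the spread of the real residuals and 200 probe sets changed. For the 24-h rhythm, 49% of 100 probe sets with an amplitude of 0.5 and 92% of 100 with an amplitude of 1 were recovered, and 11 of 4170 unchanged probe sets were called. For the day comparison, 22% of 100 probe sets with a log2 change of 0.5 and 78% of 100 with a change of 1 were recovered, with 6 of 4170 unchanged ones called. The simulated pools had independent errors per probe set and held no run effect. With 200 changed probe sets the adjusted threshold is also less strict than where few change. The recovered shares therefore overstate the power for data with few rhythmic or changed genes.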

Results

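The data describe the transcriptome of the rat SCN over 2 circadian cycles in constant darkness, with 1 pool of RNA from 5 rats at each of 8 time points. CT 0, CT 6, CT 12 and CT 18 were each sampled on both days, so that every phase had 2 pools of different animals. Each pool was read by 2 or 3 arrays, if arrays a and b of a time point are taken to read the same pool. The 10 arrays of the first run had median intensities of 136.5 to 152.3 and the 8 arrays of the technical repeat 107.9 to 127.6. Since 1 pool stands for a time point, p-values measure the spread between pools around a fitted curve, and part of that spread is array error.

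The study's title names circadian profiling as its purpose, and the first question was which transcripts followed a 24-h rhythm. Dbp, a clock-controlled transcription factor of the PAR bZIP family, followed the time of day in both cycles. Its intensity was 479 and 516 in the pools at CT 0 and 1243 and 1175 in those at CT 12, with a fitted amplitude of 0.64 ± 0.09 (SE, n = 8 pools), a peak at CT 11.7 and a peak-to-trough ratio of 2.44. Rasl11b, a small GTPase of the Ras family, peaked earlier, with 1463 and 1526 at CT 6, 523 and 490 at CT 18, an amplitude of 0.80 ± 0.09 (SE, n = 8) and a peak at CT 6.90. Bmal1, the activator at the centre of the clock's feedback loop, had its fitted peak nearly opposite to Dbp, at CT 23.3, with an amplitude of 0.48 ± 0.14 (SE, n = 8).

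Over all tested probe sets, limma called 0 of 4370 rhythmic after adjustment, 1 (Rasl11b, adjusted p = 0.0848) at an adjusted p under 0.10, and 278 at an unadjusted p under 0.05, against 218.5 given by chance. Without the 0 h pool the unadjusted count was 165. Dbp had an adjusted p of 0.166. In exact permutation tests the p was 0.00317 for Rasl11b, the smallest that the design allows but for a gene picked from all 4370, 0.00635 for Dbp and 0.0540 for Bmal1. Rasl11b and Dbp passed the adjusted threshold when only probe sets above the 75th percentile of level were tested (adjusted p = 0.00711 and 0.0192) and with limma's trend and robust options (0.0175 and 0.0456). Over all alternatives the adjusted p ranged from 0.00711 to 0.573 for Rasl11b and from 0.0192 to 0.9998 for Dbp.

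**Figure D1:**
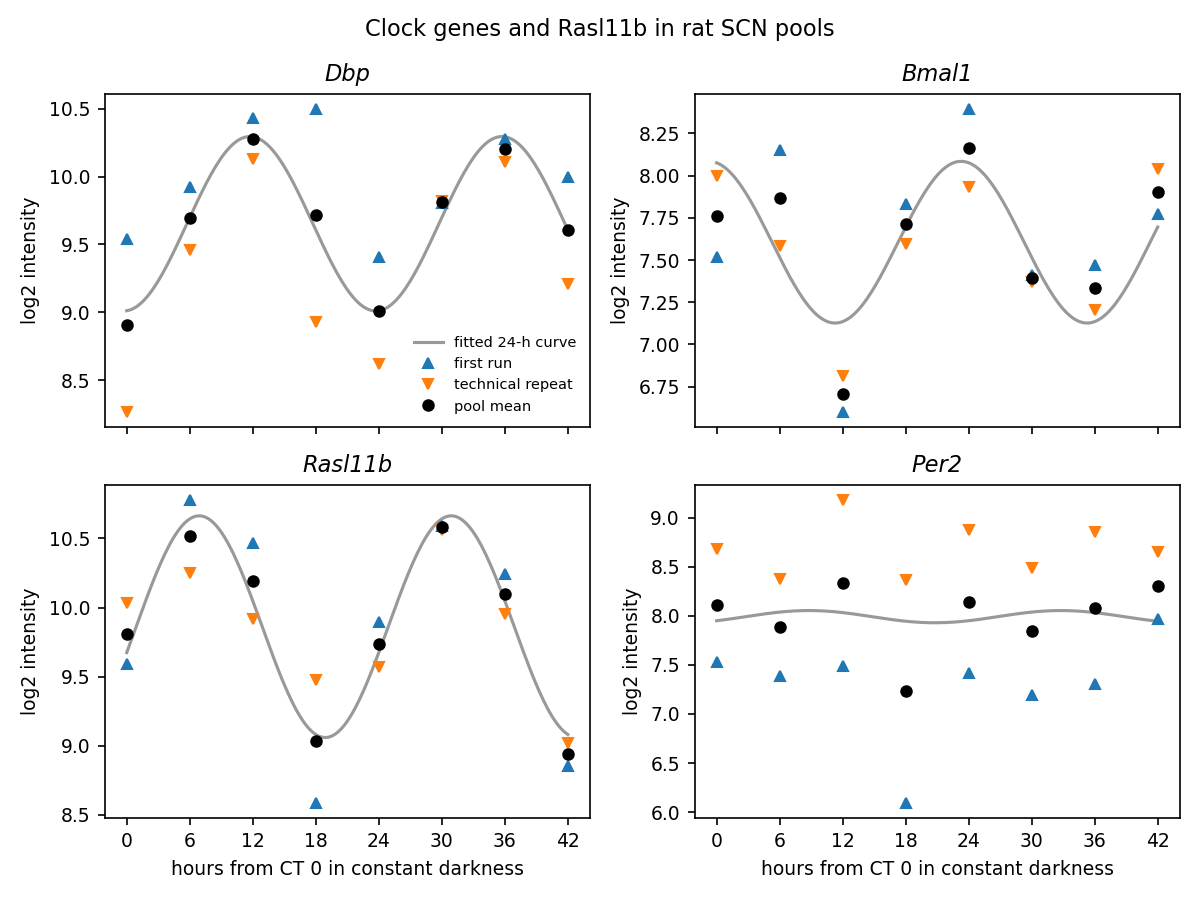
Log2 intensity (vertical axes) of Dbp, Bmal1, Rasl11b and Per2 against hours from CT 0 in constant darkness (horizontal axes); triangles are the values of the first run (upward) and the technical repeat (downward), black circles the pool means, and grey lines the fitted 24-h curves. Dbp is high at 12 and 36 h, Rasl11b at 6 and 30 h, and the Per2 values of the technical repeat lie above those of the first run at all 8 time points.

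Of the 22 genes of the core clock list, 12 were on the array and 10 were above the level filter. Adjusted over the list alone, 1 of the 10 was rhythmic (Dbp, adjusted p = 0.000760), against 0 adjusted over all genes. In the first run alone the amplitude of Dbp no longer passed over the list alone (0.48, adjusted p = 0.182, the highest of the alternatives, which went down to 5.26e-05). Bmal1 had an adjusted p of 0.0945 over the list alone. The second Dbp probe set had an amplitude of 0.44 with a peak at CT 11.5, and the second Bmal1 probe set, which lay below the level filter, an amplitude of 1.12 with a peak at CT 2.59. Nr1d1, a nuclear receptor that represses Bmal1, had an amplitude of 0.38 ± 0.18 (SE, n = 8) with a peak at CT 13.2 on its brighter probe set, and 0.50 ± 0.14 with a peak at CT 11.0 on the other. For Per2, a repressor of the clock's feedback loop, the amplitude was 0.06 ± 0.17 (SE, n = 8), so that no rhythm was detectable with these pools. Nr1d2, Tef, Hlf, Bhlhe40, Bhlhe41 and Csnk1d had amplitudes between 0.08 and 0.22 and did not pass. Rorb and Timeless, at mean intensities of 17.5 and 17.3, lay near the floor and were not tested.

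The other genes with the smallest p of the rhythm test did not pass adjustment over all genes. Kcnd3 and Cyp2e1 peaked near CT 12, at CT 10.0 and CT 12.0, with amplitudes of 0.76 ± 0.12 and 0.69 ± 0.12 (SE, n = 8). Unc119, Ssb, Serpinh1 and Kcnj16 had their fitted peaks between CT 22.8 and CT 0.351, with amplitudes of 0.64 to 0.73. Serpinh1 is a collagen chaperone and Kcnj16 an inwardly rectifying potassium channel. Ubac2 peaked at CT 19.9, Bcl2l1, which opposes cell death, at CT 17.3 and Or10al7 at CT 14.5. Ttr, the thyroid hormone carrier made by the choroid plexus, had an amplitude of 1.02 ± 0.18 with a peak at CT 6.12. A brighter Kcnd3 probe set peaked at CT 0.629 and the second Ttr probe set had an amplitude of 0.18 ± 0.28, so both genes rest on 1 probe set each. Among the 278 probe sets, 108 had their peak nearest to CT 0 and 84 nearest to CT 12, against 40 at CT 6 and 46 at CT 18.

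The comparison of CT 6 with CT 18 sets the middle of the subjective day against the middle of the subjective night. Rasl11b rose at CT 6 relative to CT 18 by 1.56 ± 0.18 on the log2 scale (SE, 2 pools per phase, adjusted p = 0.0281), and both CT 6 pools were above both CT 18 pools. It was 1 of 1 probe sets called, and 186 probe sets had an unadjusted p under 0.05, 82 of them higher at CT 6 and 104 lower. Without the 30 h pool that number was 304. A second Rasl11b probe set, dimmer than the level filter at a mean intensity of 44.1, had an amplitude of 1.29 and a peak at CT 6.31. Ttr was higher at CT 6 by 2.04 ± 0.37 and was the 1 member of the list of choroid plexus and ependyma markers that changed when adjusted over the list alone, against 0 adjusted over all genes. In every other list 0 members changed between these phases adjusted over the list alone.

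The Rasl11b call was lost without any 1 of the 8 pools (adjusted p = 0.0609 to 0.281), in either run alone (0.349 in the first run and 0.759 in the technical repeat), and without the 3 first-run arrays that had high hybridisation controls (1.33 ± 0.20, adjusted p = 0.245). It was also lost with a day term in the fit (adjusted p = 0.0727), with no level filter (0.1002) and without arrays a (0.158), at the same difference of 1.56. Over all alternatives its adjusted p ranged from 0.00228 to 0.759, and the difference without 1 pool from 1.45 (42 h) to 1.66 (6 h). The differences were 1.97 in the first run and 1.16 in the technical repeat, and the adjusted p of the rhythm was 0.573 and 0.460 within them. As Rasl11b was picked on the mean of these runs, they are no independent test of it.

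The comparison of CT 12 with CT 0 sets the end of the subjective day against its start. Dbp rose at CT 12 relative to CT 0 by 1.28 ± 0.17 on the log2 scale (SE, 2 pools per phase, adjusted p = 0.000204 over the clock list alone) and Bmal1 fell by 0.94 ± 0.28 (adjusted p = 0.0327 over the clock list alone). These 2 of 10 clock genes passed adjusted over the list alone, and 0 passed adjusted over all genes, where the adjusted p of Dbp was 0.0890. Nr1d1 was higher at CT 12 by 0.73 ± 0.36 on its brighter probe set, which stood for it in the list and did not pass. Its other probe set was higher by 0.96 ± 0.28 (limma, unadjusted p = 0.00621, against 0.00654 for Bmal1). Avp, the vasopressin gene, whose product is a main peptide of the SCN, was higher at CT 12 by 0.60 ± 0.20, and its rhythm had a peak at CT 12.8 and an adjusted p of 0.246 over the list of SCN neuropeptides alone. Dnaja1, a co-chaperone of Hsp70, was lower at CT 12 by a log2 difference of -0.89 ± 0.24 and did not pass (adjusted p = 0.0604 over the list of heat shock and protein folding genes alone). Limma called 0 probe sets over all genes, and 379 had an unadjusted p under 0.05, 183 higher at CT 12 and 196 lower, against 218.5 by chance. Without the 0 h pool the unadjusted count was 190.

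The Dbp difference was 0.89 in the first run (adjusted p = 0.0928 over the clock list alone) and 1.68 in the technical repeat (0.000194), and that of Bmal1 was -0.92 (adjusted p = 0.182) and -0.96 (0.0120). Bmal1 no longer passed without the 12 h pool (-0.60, adjusted p = 0.187) or the 24 h pool (-0.87, 0.159), with no level filter (-0.94, 0.104) or without arrays a (-0.92, 0.0596), while Dbp passed without any 1 of the 8 pools. Over all alternatives the adjusted p over the list alone ranged from 1.31e-05 to 0.0928 for Dbp and from 0.00196 to 0.187 for Bmal1. The lowest Bmal1 value came from a fit to the single arrays, which counted arrays of a pool nearly as independent replicates.

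The repeated cycle asked whether the phase differences of the first day returned in the animals of the second. Across 4370 probe sets, the difference between 12 h and 0 h correlated with that between 36 h and 24 h at r = 0.280 (Spearman's rho 0.297), and 61.4% of probe sets had the same sign on both days. Of 100 other arrangements of the pools, 1 gave a correlation as large. The difference between 6 h and 18 h did not return in this way, at r = -0.0501 (rho -0.0795) with 46.6% of the same sign and 69 of 100 arrangements as large. Dbp was among the probe sets that differed alike on both days, with intensities of 479 and 1243 at 0 and 12 h and 516 and 1175 at 24 and 36 h. The pools of both days were read in the same runs. When the first-run arrays of day 1 were set against the technical repeat of day 2, the correlation for CT 12 minus CT 0 was 0.172, with a share of 0.06 of the arrangements as large, and the other way round it was 0.0417, with a share of 0.31. Within the first run alone it was 0.237 (share 0.08) and within the technical repeat alone 0.169 (share 0.06), so that the agreement was past 0.05 in neither run and not across runs.

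The second day differed from the first in 0 of 4370 probe sets by limma after adjustment, and 173 had an unadjusted p under 0.05, 83 higher and 90 lower, fewer than the 218.5 given by chance. Without the 30 h pool the unadjusted count was 342. S100a1, a calcium-binding protein, had the smallest p. Its intensity was 233 to 321 in the pools of day 1 and 89.2 to 171 in those of day 2, a log2 difference of -1.24 ± 0.19 (SE, 4 pools per day, adjusted p = 0.423). Its other probe sets were at -0.35, -0.45 and -0.19, and the named one was at -2.04 in the first run and -0.44 in the technical repeat. Rpl11, a protein of the large ribosomal subunit, Cacna1b, a subunit of N-type calcium channels, Triobp and Ncaph2 were lower by -0.81 to -0.46. Cyp51, an enzyme of cholesterol synthesis, was higher on day 2 by 1.04 ± 0.28 on the named probe set, but by -0.01 on the brightest of its probe sets. Slfn5, Por, Tra2b and Map4k4 were higher by 0.57 to 0.76. None of these 10 genes passed. S100a1 was called when the 0 h pool was left out (-1.46, adjusted p = 0.0374; 0.0374 to 0.999 over the alternatives), the 1 call of the day comparison in any setting.

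Gene lists moved little between phases or days. Of the 63 list tests, limma's camera called 0 after adjustment. With the clock list as first matched, without Bmal1, it called 2 (adjusted p = 0.0469 for both). An unadjusted p under 0.05 was found in 11 of the 63, more than the share of 0.05 that chance gives. These tests used the preset correlation of 0.01. With an estimated correlation 0 were called, and fry called 0, with 3 at an unadjusted p under 0.05. With an estimated correlation camera has only the few residual degrees of freedom of the fit, so that little could pass over 63 tests. Pan-neuronal markers on the second day went from an unadjusted camera p of 0.01135 to 0.0580, although their estimated correlation was negative (-0.04). The adjusted p with an estimated correlation therefore cannot show that a list call was false. Few degrees of freedom are not the only difference, however. For ribosomal proteins on the second day the estimated correlation was 0.34, far above the preset 0.01. Their unadjusted camera p went from 0.00103 to 0.348. Where the genes of a list move together like this, the p with the preset correlation is likely too small. The ribosomal protein list came nearest, with a median log2 difference of -0.13 on the second day over 36 genes, 28 of them lower (adjusted p = 0.0648, and adjusted p = 0.912 with an estimated correlation). It passed without the 0 h, 6 h or 30 h pool, at medians of -0.16, -0.17 and -0.19 (with an estimated correlation, adjusted p = 0.911, 0.8145 and 0.867). However, its median was -0.01 without the 18 h pool (adjusted p = 0.878), -0.06 without 36 h and -0.08 without 42 h. The direction also differed between the runs, at -0.30 in the first run and 0.07 in the technical repeat. Without the 36 h pool ribosomal proteins passed at CT 12 relative to CT 0, at 0.22 (adjusted p = 0.939 with an estimated correlation). With all pools that median was 0.13 (adjusted p = 0.962 with an estimated correlation). The heat shock and protein folding list had a median of -0.15 at CT 12 relative to CT 0, with 13 of 17 genes lower (adjusted p = 0.2005), from runs that went opposite ways, at 0.14 in the first run and -0.51 in the technical repeat. The core clock list had a median of 0.23, with 9 of 10 genes higher (adjusted p = 0.229). The median, the mean and the direction of the test differed in sign in 12 of the 63 list tests, with medians of up to 0.09.

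In the rhythm test, 0 members of any list passed adjusted over all genes. Adjusted over the list alone, 1 passed in the clock list (Dbp) and 1 in the list of choroid plexus and ependyma markers (Ttr, adjusted p = 0.00404), and 0 in each of the other lists. Neuropeptides, receptors and immediate early genes held 10, 6 and 13 tested genes. Avp, Nmu and Penk had the smallest p among the neuropeptides, Grin2b and Gria2, both glutamate receptor subunits, among the receptors (adjusted p = 0.342 over the list alone for both), and Egr1, Nr4a2 and Atf3 among the immediate early genes (0.335). Egr1, a transcription factor induced by neuronal activity, had an amplitude of 0.42 ± 0.13 with a peak at CT 8.99. Glycolysis was led by Pdk2 (adjusted p = 0.315 over the list alone), oxidative phosphorylation by Cox4i1 (0.450), cholesterol and fatty acid synthesis by Acly (0.591), ribosomal proteins by Rpl17 (0.762) and the proteasome by Psma7 (0.811). Synaptic vesicle release was led by Dnm1 (0.312), GABA signalling by Slc6a11 (0.753), potassium and calcium channels by Cacnb3 (0.371) and cAMP, calcium and MAP kinase signalling by Adcy6 (0.794).

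Markers of other cells that a dissection could hold were tested in the same way. Pmch, the melanin-concentrating hormone gene of the lateral hypothalamus, led the neighbouring hypothalamic neurons, with an amplitude of 0.60 ± 0.13, a peak at CT 21.2 and an adjusted p of 0.0523 over the list alone. Fabp7, a fatty acid binding protein of astrocytes, led the astrocyte markers (adjusted p = 0.0615 over the list alone). The leading genes of the oligodendrocyte, vessel, microglia and pan-neuronal markers were Ugt8, Kdr, Cd74 and Snap25, with adjusted p over the list alone up to 0.532. The largest median of any list was that of the oligodendrocyte and myelin markers, -0.29 at CT 12 relative to CT 0, which did not pass.

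The labels call the second set of arrays a technical replicate of the same time points. Whether its RNA was labelled anew or only hybridised again, and what sets arrays a and b apart, is not given in the sources used here, so that the spread between arrays of a pool may hold more than hybridisation error. Levels correlated between runs at 0.833 (18 h) to 0.914 (24 h) across probe sets. The deviations of a pool from the mean of its run were only weakly shared, with a mean correlation of 0.0662 between the runs of the same pool and -0.00914 between different pools. Of 8 pools, 3 matched themselves best (6, 24 and 36 h), and 814 of 40320 assignments of the pools gave a mean as high (exact permutation p = 0.0202, one-sided). The mean difference between the runs had a median size of 0.39 per probe set on the log2 scale. After it was taken out, the median SD between the 2 runs of a pool was 0.30. The median SD between pool means was 0.23, against 0.21 that this spread between runs would give alone. Per2 shows the run difference for a clock gene, with log2 values of 6.10 to 7.97 in the first run and 8.36 to 9.18 in the technical repeat. Rasl11b had amplitudes of 1.03 and 0.58 in the 2 runs and Dbp 0.48 and 0.89, with Dbp peaks at CT 13.6 and CT 10.8.

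The hybridisation controls, bacterial transcripts added to every sample, differed between arrays. On the first-run arrays of 12 h, 18 h and 36 h (array b) they were 2.30, 2.38 and 3.06 times the level of the other first-run arrays. These are pools of CT 12 and CT 18, which enter the comparisons described above. The 12 h and 18 h arrays are the only first-run arrays of their pools. Without them these pools rest on the technical repeat alone, so that the setting leans on that run and is no separate check. Without these 3 arrays, which were left out as an alternative chosen after seeing the data, 0 probe sets passed the rhythm test, CT 12 minus CT 0 and CT 6 minus CT 18 by limma, with 287, 334 and 229 at an unadjusted p under 0.05. There, Dbp rose by 1.30 ± 0.19 between CT 0 and CT 12 (adjusted p = 0.000544 over the clock list alone) and Bmal1 fell by 0.93 ± 0.25 (0.0206).

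**Figure D2:**
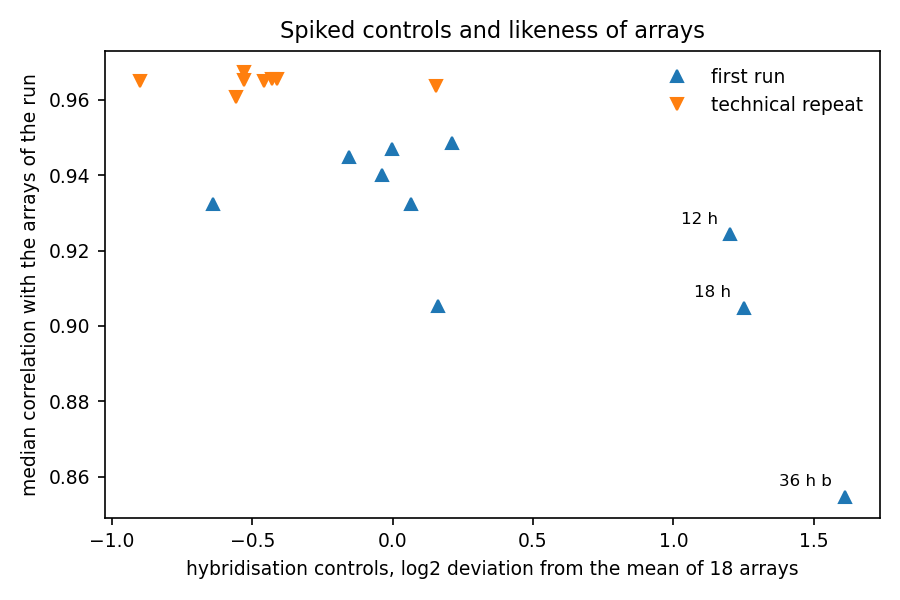
Median correlation of each array with the other arrays of its run across tested probe sets (vertical axis) against the level of the hybridisation controls as a log2 deviation from the mean of all 18 arrays (horizontal axis); upward triangles are the 10 first-run arrays and downward triangles the 8 arrays of the technical repeat. The 3 named first-run arrays have controls at 1.20, 1.25 and 1.61, and array b of 36 h has the lowest correlation, 0.855.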

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

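The tests on marker lists of other cells, on the order of the pools and on the controls against the likeness of arrays were chosen only after the results they bear on had been seen, and so was leaving out the 3 first-run arrays with high hybridisation controls.

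Among the 10 first-run arrays, array b of 36 h stood apart from the others by its median correlation with them, 0.855, against 0.905 for the next array. At 0 h the ratio of the 3' to the 5' GAPDH control was 8.55 in the first run, against 21.7 for the next array, while its actin ratio was 17.0, second in the run to the 18 h array, which had the highest of both ratios (35.2 for GAPDH and 20.9 for actin). The 3' signal was above the 5' signal on all 18 arrays, with ratios of 8.55 to 35.2 for GAPDH and 2.02 to 20.9 for actin. This bias to the 3' end limits all arrays, and its cause was not tested. Without the 0 h pool, which holds the array with the low GAPDH ratio, the unadjusted CT 12 minus CT 0 count was 190. Whether the ratios bear on that count was not tested. In the technical repeat the hybridisation controls of 42 h were at a log2 deviation of 0.15, against -0.41 for the next. Several measures were looked at in both runs, and chance alone flags about 1 in 20 such groups.

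For the likeness of arrays, a weaker sample signal relative to the controls is a candidate explanation. Over the 10 first-run arrays the control level and the median correlation were related at r = -0.739 (permutation p = 0.0108, adjusted 0.0216) and Spearman's rho of -0.590 (permutation p = 0.0772, adjusted 0.0772), 2 measures of 1 relation. Without the 2 arrays farthest in control level (36 h b and 18 h), r was -0.276, so that the relation rests on those arrays. Over all probe sets, which were tried first, rho was -0.651, beyond the bound set for this explanation, which the value over the tested probe sets did not reach. The relation stays open, and no biological explanation was tested.

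The excess of probe sets that differed between CT 12 and CT 0 (379 at an unadjusted p under 0.05) did not exclude chance, since 11 of 100 arrangements of the pools, the labelled one included, gave as many and the highest of the others gave 526. Without the 0 h pool the count was 190. Without the 3 arrays the count was 334, still above the 218.5 given by chance. There the 12 h and 18 h pools rest on the technical repeat alone, so that this count cannot exclude weak signal on the 3 arrays. Cells of another type may contribute, as the largest median among their marker lists was -0.29 (8 oligodendrocyte and myelin genes, which did not pass), while its most abundant members, Mobp at a mean intensity of 16700 and Mbp at 6742, were at 0.18 and -0.42. These stay open, as does a biological difference between the phases, which was not tested apart from them.

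The weak sharing of pool deviations between the runs was also present in the 6 pools that could be compared without the 3 arrays. Their mean correlation of a pool with itself was 0.0552, against 0.0702 with all arrays. For these 6 pools the 3 arrays thus did not explain the weak sharing. The 12 h and 18 h pools have no other first-run array and are in neither value, so that for them this was not tested. Pools out of order in 1 run stay open: the highest of the assignments gave 0.114, and the labelled order was among the highest 5% with all arrays (exact permutation p = 0.0202) but not without arrays a (0.0776). Dim probe sets could account for part of it, since the correlation was 0.148 over the brightest 437 probe sets, and this stays open. The small size of the differences between pools relative to array error was not tested apart from this.

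For the other comparisons chance was not excluded either. In the rhythm test 25 of 100 arrangements gave 278 or more probe sets at an unadjusted p under 0.05 (highest of the others 578), for CT 6 minus CT 18 63 of 100 gave 186 or more (highest 628), and for the days 24 of 35 splits gave 151 or more under the day term alone (highest 544). The medians over the arrangements were 213.5 for CT 6 minus CT 18 and 182 for the days; whether the high counts of single arrangements come from a structure of the pools or from noise shared between probe sets was not tested. A call after adjustment for CT 6 minus CT 18 appeared in 4 of 100 arrangements, the labelled one included.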

How the results depend on the processing

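The setting without the 3 first-run arrays was chosen after seeing the data. The clock list without Bmal1 is the list as first matched, under an older symbol of that gene. It was added as an alternative after seeing the data. Causes of the changes below were not tested, except that stricter or absent filters change the number of probe sets tested. List tests with an estimated correlation had few degrees of freedom, as described above, and cannot decide the list calls below. Nor can those with the preset correlation for ribosomal proteins, whose estimated correlation was 0.34 on the second day with all arrays.

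Rhythmic probe sets after adjustment were 0 in 20 of 26 alternatives. There were 2 above the 75th percentile and 2 with trend and robust (Dbp and Rasl11b), 1 in the technical repeat alone, 1 in the array-level fit with the run as a replicate block and the pool as a random block (Rasl11b), 1 at an adjusted p under 0.10 and 278 without adjustment. Leaving out a pool gave 0 to 0. In the array-level fit the correlation between arrays of a pool was estimated at -0.037. That fit thus counted the arrays nearly as independent replicates, and its call does not rest on pools. At an unadjusted p under 0.05 the rhythm count was 569 with no level filter, 141 above the 75th percentile, 167 in the first run alone and 101 with the 18 arrays as if independent, and 165 to 367 without 1 pool.

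For CT 6 minus CT 18 the 1 call became 0 with no level filter, in the first run, in the technical repeat, without arrays a, without the 3 arrays, with a day term, and without any 1 pool (0 to 0). Its unadjusted counts were 474 with no filter, 99 above the 75th percentile, 112 without arrays a, 70 with 18 arrays and 164 to 304 without 1 pool. For CT 12 minus CT 0, calls were 1 above the 75th percentile, 1 with trend and robust (Dbp both times) and 2 in the technical repeat, and 0 to 0 without 1 pool. Unadjusted counts were 728 with no filter, 210 above the 75th percentile, 183 with 18 arrays and 190 (without 0 h) to 438 without 1 pool. The day comparison gave 0 to 1 without 1 pool, and unadjusted counts of 449 with no filter, 90 above the 75th percentile, 296 without arrays b and 134 to 342 (without 30 h).

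The agreement of the cycles at CT 12 minus CT 0 fell to 0.2502 without arrays a, 0.237 in the first run, 0.169 in the technical repeat, and 0.172 and 0.0417 across runs, with shares of 0.07, 0.08, 0.06, 0.06 and 0.31 of the arrangements as large; the own-pool correlation was 0.0488 without arrays a and no longer passed (exact permutation p = 0.0776).

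List calls, of which 0 of 16 passed with an estimated correlation (adjusted p = 0.753 to 0.957), were 1 above the 75th percentile, 1 with trend and robust and 1 in the first run (ribosomal proteins on the second day each time), 4 in the technical repeat (heat shock and ribosomal proteins at CT 12 minus CT 0, oxidative phosphorylation and pan-neuronal markers on the second day, adjusted p = 0.881 for each with an estimated correlation), 1 without the 3 arrays (heat shock at CT 12 minus CT 0, adjusted p = 0.838 with an estimated correlation), 2 with the mean of all probe sets (heat shock at CT 12 minus CT 0 and ribosomal proteins on the second day, 0.753 and 0.895), 2 for the clock list without Bmal1 (clock at CT 12 and ribosomal proteins, adjusted p = 0.0469 for both, where Bmal1 is the 1 clock gene of 10 that was lower; with an estimated correlation, adjusted p = 0.865 and 0.912) and 0 to 1 without 1 pool (ribosomal proteins, on the second day without 0, 6 or 30 h and at CT 12 minus CT 0 without 36 h). Oxidative phosphorylation on the second day, mixed in sign over both runs (median 0.01, 16 of 28 genes higher, test direction down), was called in the technical repeat at 0.10 (adjusted p = 0.0419, and adjusted p = 0.881 with an estimated correlation). In the first run it went the other way, at -0.10 with 17 of 28 genes lower (camera, adjusted p = 0.5035). Over all genes, the rhythm and day tests had 0 calls to lose. Of their 2398 named-gene values under alternatives, 2392 did not pass and 6 passed. Of 2181 peaks, 14 moved by over 6 h. Phase differences are not counted. The Rasl11b call at CT 6 minus CT 18 was kept in 9 of 23 alternatives. That of Bmal1 at CT 12 minus CT 0, adjusted over the clock list alone, was kept in 17 of 22. Signal over the floor limits dim probe sets such as Rorb and Timeless.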

Other observations

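Both runs were tested alone by design, while the single heat shock genes and the setting without 3 arrays were chosen after their values were seen. The adjusted p with an estimated correlation rests on few degrees of freedom here too and cannot decide the list calls. For ribosomal proteins on the second day the correlation estimated with all arrays was 0.34. Their camera p with the preset 0.01 is therefore likely too small.

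Heat shock and protein folding genes were lower at CT 12 than at CT 0 in the technical repeat, where the median of 17 genes was -0.51 and 15 of them were lower (limma's camera, adjusted p = 4.25e-06, and adjusted p = 0.881 with an estimated correlation). Adjusted over the list alone, 4 fell there: Canx and Hspa5, chaperones of the endoplasmic reticulum, by -1.03 ± 0.25 and -0.65 ± 0.18, Dnaja2 by -0.99 ± 0.25 and Fkbp4, a co-chaperone of Hsp90, by -0.74 ± 0.23 (SE, 2 pools per phase). In the first run the median was 0.14, with 9 of 17 genes higher, and Canx was at 0.52 ± 0.30. Ribosomal protein genes went the other way in the technical repeat, with a median of 0.21 at CT 12 relative to CT 0 and 31 of 35 genes higher (adjusted p = 0.00994, and adjusted p = 0.881 with an estimated correlation). In the first run their median was 0.06, with 21 of 36 genes higher (camera, adjusted p = 0.861). Without the 3 first-run arrays with high hybridisation controls the heat shock median was -0.36 (adjusted p = 0.000173, and adjusted p = 0.838 with an estimated correlation). There the 12 h and 18 h pools rest on the technical repeat alone, so that this median leans on the run that gave -0.51. Dnaja1 was at -0.72 ± 0.35 and -1.06 ± 0.37 in the 2 runs and passed in neither (adjusted p = 0.367 and 0.0548 over the list alone).

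Ribosomal protein genes were lower on the second day in the first run, with a median of -0.30 and 32 of 36 genes lower (adjusted p = 1.98e-07, and adjusted p = 0.957 with an estimated correlation). In the technical repeat of the same pools the median was 0.07, with 23 of 35 genes higher. Without the 3 arrays, where the 12 h and 18 h pools rest on the technical repeat alone, it was -0.04, with 14 of 36 higher (adjusted p = 0.611). Across probe sets, the day differences of the 2 runs correlated at 0.00469, against 0.190 for CT 12 minus CT 0 and 0.102 for CT 6 minus CT 18. Pan-neuronal markers were higher on the second day in both runs, with medians of 0.14 and 0.21 over 9 genes, and passed in the technical repeat (adjusted p = 0.0271, and adjusted p = 0.881 with an estimated correlation) but not in the first run (adjusted p = 0.752). Over both runs no marker list passed. Microglia markers had a median of 0.14 with 9 of 10 genes higher, choroid plexus and ependyma markers 0.24 with 4 of 5 higher, and neighbouring hypothalamic neurons -0.16 with 8 of 13 lower.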
